A study of Rattus norvegicus with 35 samples.

How the data were processed

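The series holds bulk RNA sequencing of hippocampus from 35 rats in 7 groups of 5. Per the labels, stranded poly(A) libraries were made from RNA with a quality value above 7 and sequenced as paired-end reads of 100 bp with a target of 30 M reads (M for mega). Animals were 6 months old at surgery and were treated for 7 days after a washout of 2 weeks, at doses per kg of 0.16 mg estradiol, 3.23 mg tamoxifen, 9.68 mg raloxifene, 0.16 mg exemestane and 4.03 mg anastrozole. The doses are given as the labels state them; the exemestane dose equals that of estradiol, and whether the doses of exemestane and anastrozole were exchanged in the labels could not be checked.

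The authors quantified the reads with Salmon and deposited expected counts per gene, held as whole numbers and not scaled for depth. A second deposited table holds a normalized signal that the authors made with DESeq2. It equals the counts divided by a factor that differs by gene and library. The annotation, genome build and tool versions the authors used are not stated, so no gene positions are given. Of the genes, 13092 symbols matched the RefSeq genes of the rat, and 1132 entries carry an Ensembl identifier only. The table had been filtered, since every gene has counts in at least 8 libraries, and the lowest sum over libraries is 86. All columns matched 1 library each. Library titles carry no shared numbers, so replicates are not paired.

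Totals ran from 5.58 M to 12.09 M counts, with a median of 8.01 M, and the median gene had a mean of 151 counts. Replicates of a group varied by 2.53 to 35.8 times what counting error alone gives (chi-squared per degree of freedom), and the common biological coefficient of variation was 0.152. Over all genes the spread between libraries was therefore larger than counting error, while genes of low counts are limited by depth as well.

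The choices named next were made before the data were examined: groups, comparisons, tests, gene lists, the rule for named genes and the first set of alternatives. Counts were tested in edgeR 4.0.16 under R 4.3.3 with TMM factors, filterByExpr by group, and the robust quasi-likelihood F-test on all 35 libraries with 7 groups. Adjusted p values are Benjamini-Hochberg over the 14411 genes that passed the filter, with a threshold of 0.05 and no fold threshold. The 12 comparisons were the 6 groups against vehicle, tamoxifen against raloxifene, exemestane against anastrozole and each of the 4 drugs against estradiol, followed by 1 test of any difference among the 7 groups. Standard errors of log2 fold changes were taken from the fold and its F statistic. CPM values use TMM-scaled totals, and intervals have 95% confidence.

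Gene lists for pathways, cell types, neighbouring tissues and RNA quality, 36 in all, were tested with camera of limma 3.58.1 on log-CPM with a prior count of 2. The correlation between genes was estimated from the data, and the preset value of 0.01 served as an alternative. A test of each list against no change (fry), rather than against the other genes, was run as well and is not used here. Lists with fewer than 4 tested members had no list test. A count adjusted over the list alone uses the same gene tests with the adjustment made within the list. The mean log2 CPM of cell type lists was compared with an exact two-sided permutation test of 126 splits, whose smallest p is 0.0079. Similarity to estradiol was the Pearson correlation across genes, set beside 1000 simulated pairs of unchanged groups that share their controls.

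Named genes followed a fixed rule. In each comparison with vehicle and each comparison within a drug class it took, among called genes with a symbol, at least 1 CPM and the same direction in at least 4 of 5 libraries, the 12 with the largest rise and the 12 with the largest fall. It added up to 4 called members per list, the 10 genes of smallest p where fewer than 10 passed, a fixed set of steroid receptor and aromatase genes throughout, and the 5 genes of smallest p against estradiol and among the groups. A choice of these is printed, and the results of some genes are not reported here. Named outside the rule, after their values were seen, were Vgf in sham and in the comparisons of drugs with estradiol, Ptn against estradiol, Mt-ENSRNOG00000030478 in estradiol, Chm, Ccdc88a, Chpf, UNKNOWN_ENSRNOG00000062127, Nr1d2, the list members given for sham, estradiol, tamoxifen and anastrozole, Rn7sl1, Ttr and the 4 genes called among groups with class. So were UNKNOWN_ENSRNOG00000055825 and UNKNOWN_ENSRNOG00000061297 in estradiol.

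Library class was defined after the data were seen. The log ratio of the 2 deposited tables was centred by gene over 13977 genes, and its first component held 87.5% of the variance, against 0.717% for the second. Its sign split the libraries into 20 of class A and 15 of class B. The first component of expression held 23.1% of the variance and correlated with class (r = 0.942). The second held 17.1% and correlated with the score of the choroid plexus list (r = 0.938), a list for which 0 of 14 members passed in any comparison with vehicle. Sham and estradiol have no class B library and raloxifene has no class A library, so class and group are told apart only through the other groups and 1 vehicle library. Several adjustments were tried, and the values of each are given.

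Alternatives fixed beforehand were DESeq2 1.42.0, RLE size factors, no filter, only the 2 groups compared, the choroid plexus score as a covariate, surrogate variables from sva 3.50.0 (2 were found) and leaving out each library in turn. For lists they were the preset correlation, a prior count of 5, voom weights and the choroid plexus score, and for similarity a prior count of 5, a minimum of 10 CPM and split controls. Added after the data were seen were library class as a covariate, class with the choroid plexus score, the authors' per-gene factors as offsets, each class alone, class with the preset correlation, and class with split controls. No scaling moved the median of all genes by more than 0.1.

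The procedure was tested on simulated data with the depths of these libraries and the spread per gene that remained with class in the model. The designed fit of the real libraries holds class differences as well, so its spread is wider. For estradiol against vehicle with 200 changed genes and no class effect, 27 of 67 were recovered at a log2 fold of 0.3, 55 of 67 at 0.5 and 64 of 66 at 1. Of 153 calls, 7 were false. With a simulated class effect and no treatment effect, raloxifene against vehicle gave 1621 calls without class in the model and 0 with it, and exemestane and estradiol gave 0 either way. With 200 changed genes and a class effect, estradiol against vehicle recovered 16, 42 and 63 of them without class in the model and 23, 49 and 65 with it, at the same 3 folds. With class in the model, raloxifene against vehicle recovered 13 of 67, 39 of 67 and 62 of 66. The other comparisons were not simulated. A list of 18 genes shifted by 0.3 gave a camera adjusted p of 2.63e-11, and 0 other lists were called. The simulated genes varied independently of each other, so this does not show the power of list tests where genes are correlated. Intervals and floors cover counting and replicate error only, and a gene at 0 in all libraries of a group is taken as at most 3 counts per library.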

Results

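Gene expression was measured by RNA sequencing in the hippocampus of female rats that were sham-operated or ovariectomised at 6 months of age. After a 2-week washout the ovariectomised animals received vehicle, 17β-estradiol, a selective estrogen receptor modulator (tamoxifen or raloxifene) or an aromatase inhibitor (exemestane or anastrozole) for 7 days. Each of the 7 groups held 5 libraries, 35 in all. Assigned counts per library ran from 5.58 M to 12.09 M (M for mega). Their mean was 9.22 ± 2.03 M in sham, 8.05 ± 0.878 in vehicle, 6.58 ± 1.1 in estradiol, 7.75 ± 1.95 in tamoxifen, 8.79 ± 1.15 in raloxifene, 7.88 ± 0.849 in exemestane and 9.21 ± 1.92 in anastrozole (SD, n = 5 each). Of the genes listed, 14411 were tested.

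The libraries fell into 2 classes that the labels do not name, whose origin was not tested and that are partly confounded with the groups. Rn7sl1, the RNA of the signal recognition particle, took 4.47 to 6.49% of the counts in 20 libraries, here called class A, and 2.90 to 3.84% in 15 libraries, class B. Mitochondrially encoded protein genes took 4.32 to 6.66% in class A and 5.80 to 7.77% in class B. Class B held all 5 raloxifene libraries, 4 of 5 exemestane, 3 of 5 tamoxifen, 2 of 5 anastrozole, 1 of 5 vehicle and 0 of the sham and estradiol libraries. Class was defined from the per-gene factors the authors applied, not from any outcome, and only after the data had been seen. In a fit with group and class together, 7473 genes differed between the classes, 3677 higher and 3796 lower in class B. Each comparison is therefore given as designed, with its count when class is a term in the model and, for genes that class moved most, the folds in both fits. Ttr, the transthyretin made by choroid plexus, ranged from 0.862 to 2770 CPM in class A and from 0.495 to 2767 CPM in class B, so choroid plexus tissue entered some dissections of both classes.

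**Figure D1:**
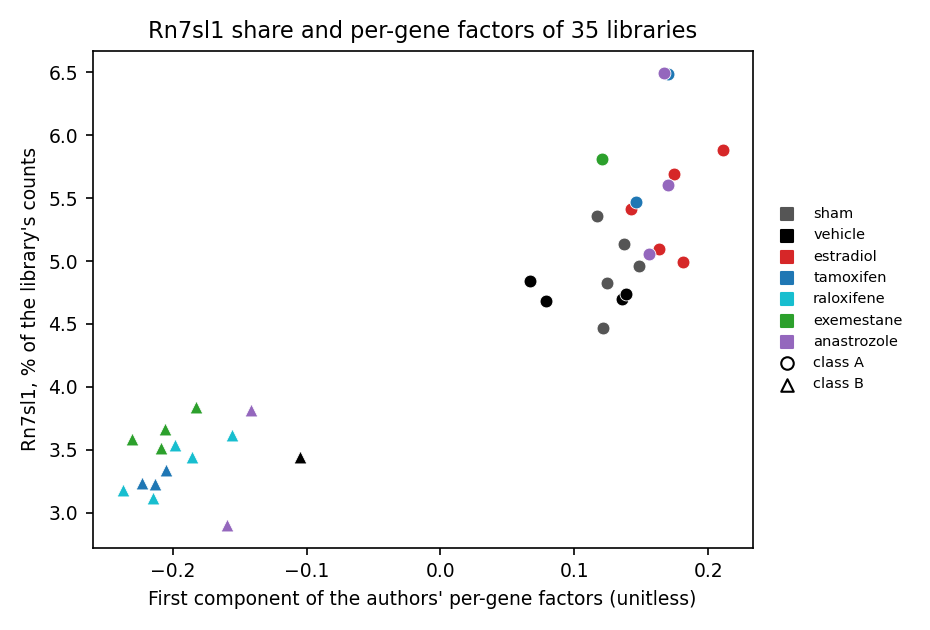
Share of counts assigned to Rn7sl1 (percent, y axis) against the first component of the authors' per-gene factors (unitless, x axis) for the 35 libraries. Colours are groups and symbols are classes: the 20 class A libraries lie at 4.47% or more, and the 15 class B libraries at 3.84% or less.

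The first comparison, sham-operated against ovariectomised vehicle animals, asks what loss of the ovaries changes in the hippocampus. Tpbg, a membrane glycoprotein that dampens Wnt signalling, stood at 13.8 ± 5.84 CPM in sham and 6.53 ± 0.923 in vehicle (SD, n = 5), a log2 fold change of 1.09 ± 0.21 (SE). Tacr3, the neurokinin B receptor, differed by 0.83 ± 0.17, the clock output gene Dbp by -0.55 ± 0.11, the glutathione transferase Gstp1 by -0.42 ± 0.085 and the period gene Per3 by -0.38 ± 0.077, each with an adjusted p of 0.0635 in edgeR. Hspa5, the main chaperone of the endoplasmic reticulum, stood at 297 ± 45.3 against 215 ± 20.8 CPM. Vgf, a neuropeptide precursor induced by neurotrophins, was at 117 ± 2.93 against 83.1 ± 17.8 CPM. Of the 18 heat shock and unfolded protein response genes, 6 rose when adjusted over the list alone and 0 over all genes, Hspa5, Manf and Xbp1 among the 6. The list's camera call at the preset correlation (adjusted p 2.58e-06) was lost with an adjusted p = 0.0567 with an estimated correlation. Adjusted over the list alone, 4 of 16 circadian genes fell and 1, Arntl, rose; the list's adjusted p with an estimated correlation was 0.6. The thalamic marker Tcf7l2 was among 2 of 10 thalamus and habenula genes higher in sham over the list alone, with sham replicate 1 at a mean of 4.22 log2 CPM for that list and the others at 2.72 to 3.12.

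For sham against vehicle, edgeR called 0 genes, with 981 at an unadjusted p under 0.05, and DESeq2 called 14. With class in the model edgeR called 6 genes, Vgf, Tpbg, Tacr3, Dbp, Gstp1 and Per3, each at an adjusted p of 0.0466. That count was 0 without sham replicate 2 or 3 or vehicle replicate 2, 4 or 5, 1 without vehicle replicate 3, 2 without sham replicate 5 or vehicle replicate 1, and 0 in the class A libraries alone. Of these 10 fits without a library, Vgf passed in 3 and Tpbg, Tacr3, Dbp, Gstp1 and Per3 in 1 each.

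The next comparison, estradiol against vehicle, asks what the hormone restores after ovariectomy. One entry passed the test as designed: Mt-ENSRNOG00000030478, a mitochondrial transcript without a symbol, rose from 666 ± 170 to 1070 ± 61.1 CPM (SD, n = 5), a log2 fold change of 0.68 ± 0.12 (SE) with an adjusted p of 0.0377. It passed in 2 of the 10 fits that leave out 1 library, not without estradiol replicates 1, 2 and 4 or vehicle replicates 2, 3, 4 and 5, where the count was 0. What kind of RNA this entry is could not be checked. Mitochondrial entries without a symbol together took 3.29 to 5.62% of the counts in class A and 5.14 to 7.10% in class B. In the fit with class 43 genes passed, 32 of which rose and 11 of which fell. Many of those that rose carry an Ensembl identifier only, and no such entry fell. Among them were UNKNOWN_ENSRNOG00000055825 (0.79 ± 0.17, 1930 ± 241 against 962 ± 332 CPM) and UNKNOWN_ENSRNOG00000061297 (0.57 ± 0.11, 1780 ± 215 against 1070 ± 235 CPM). What these entries are could not be checked, and the genes named next are those with a symbol. Vgf rose by 0.54 ± 0.078 (adjusted p 0.000541; 129 ± 10.8 against 83.1 ± 17.8 CPM; 0.63 ± 0.14 and 0.147 as designed). Fkbp4, a cochaperone of steroid receptors, rose by 0.27 ± 0.05 (adjusted p 0.0152; 0.096 as designed), and Stip1, which links Hsp70 to Hsp90, rose by 0.23 ± 0.046 (0.0255; 0.118 as designed). Cox17, a copper chaperone for cytochrome oxidase, and Eng, the endothelial coreceptor endoglin, rose by 0.48 ± 0.11 and 0.45 ± 0.097 in that fit. Pon2, a lactonase with antioxidant action, fell by 0.35 on the log2 scale, and the clock genes Dbp, Per3 and Nr1d2 fell by 0.53, 0.34 and 0.36. Cnp, an enzyme of myelin, fell by 0.43 ± 0.097. In the class A libraries alone, 9 of the same 10 libraries, 9 genes passed. Of the genes with a symbol named here only Vgf (edgeR adjusted p 0.00582) and Nr1d2 (0.0128) were among them, with Fkbp4 at 0.0558 and Stip1 at 0.0779. Both UNKNOWN entries named above were among them too.

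Of the 18 heat shock and unfolded protein response genes, 7 rose under estradiol when adjusted over the list alone and 0 over all genes, with Sdf2l1 at a log2 fold change of 0.84 ± 0.23, Hspa5 at 0.40 ± 0.11 and Xbp1 at 0.26 ± 0.068. The list's adjusted p with an estimated correlation was 0.14, against 1.36e-05 at the preset one. Of 15 oligodendrocyte and myelin genes, 5 fell over the list alone, with Opalin at -0.53 ± 0.14 and Cnp at -0.40 ± 0.099, and all 15 folds were negative; the adjusted p with an estimated correlation was 0.356. The mean myelin score lay -0.347 log2 CPM from vehicle (exact two-sided permutation p 0.0159, 0.381 after adjustment over 48 tests), and -0.253 (exact p 0.0238) without vehicle replicate 4, whose score of 7.82 stood apart from the 7.28 to 7.42 of the others. The myelin score lay below vehicle in all 6 groups, from -0.142 in raloxifene to -0.347 in estradiol, with sham at -0.16. All share the same vehicle libraries. A level particular to vehicle therefore cannot be told apart from separate responses, also for the myelin genes named below. All 13 mitochondrially encoded protein genes had negative folds (median -0.254), and 0 passed the test over all genes or over the list alone. Of 19 estrogen-responsive genes tested, 0 passed over all genes and 1, Xbp1, rose over the list alone; the median fold was 0.0311 and the mean -0.0247 (adjusted p with an estimated correlation 0.708). Esr1, Esr2, Gper1, Pgr and Cyp19a1 did not pass in any comparison. Their medians over 35 libraries were 2.44 CPM for Esr1, 1.08 for Esr2, 0.858 for Gper1, 22.8 for Pgr and 1.12 for Cyp19a1.

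**Figure D2:**
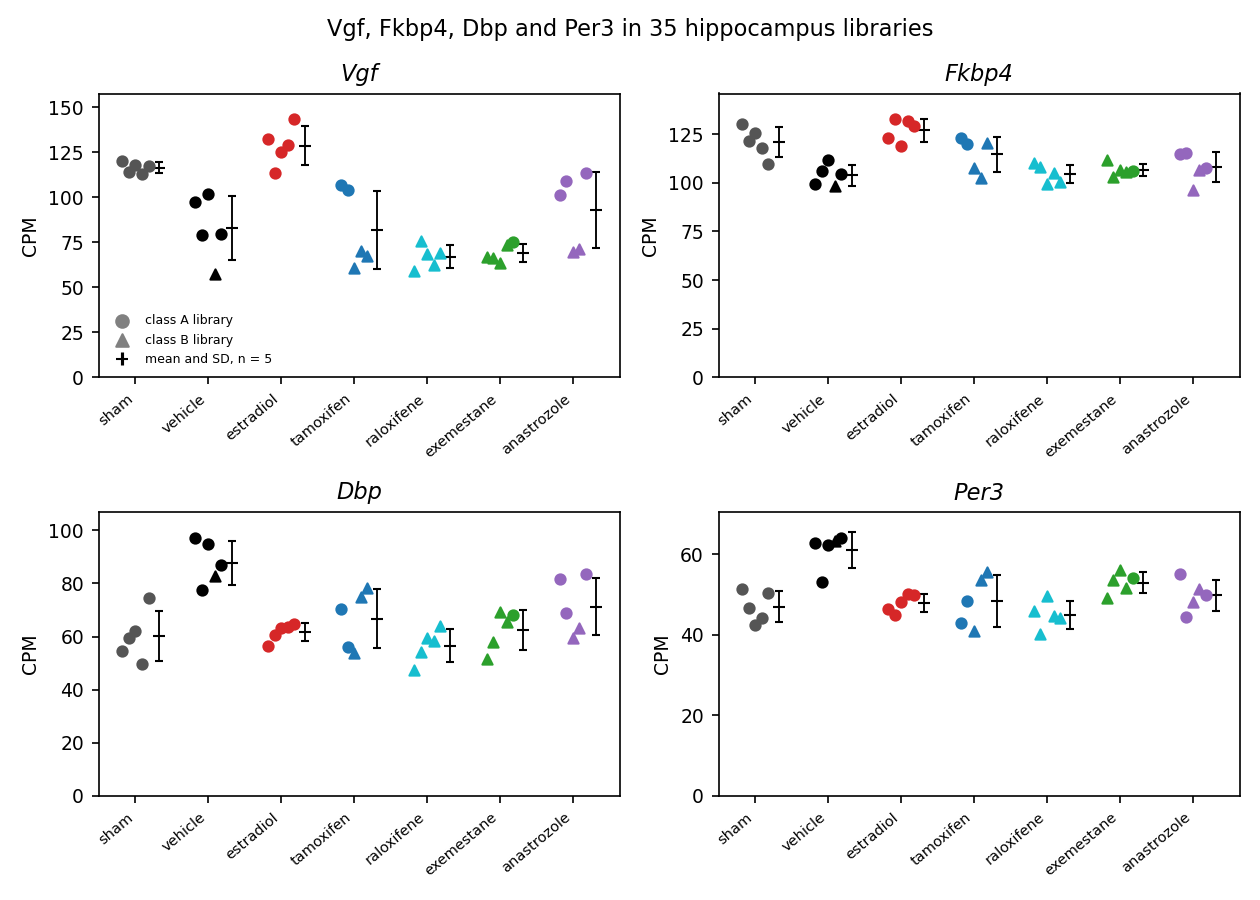
Expression (CPM, y axis) of Vgf, Fkbp4, Dbp and Per3 in each library of the 7 groups, with circles for class A, triangles for class B and the mean ± SD of 5 libraries beside them. Vgf stood at 129 ± 10.8 CPM in estradiol and 83.1 ± 17.8 in vehicle, and its class B libraries lay below the class A libraries of the same group in tamoxifen and anastrozole.

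The estradiol count with class in the model was 2 without vehicle replicate 5. It was 9, 10, 9, 8, 17 and 17 without vehicle replicates 3 and 2 and estradiol replicates 4, 5, 1 and 3, so the size of the count rests on single libraries. Of 10 such fits, Vgf passed in all 10, Pon2 in 9 (log2 fold change -0.38 to -0.31), Mt-ENSRNOG00000030478 in 9 (0.54 to 0.78), Fkbp4 in 8 (0.25 to 0.29), Stip1 in 6 (0.22 to 0.26), Cox17 and Eng in 4, Dbp in 3, Per3 and Nr1d2 in 2 and Cnp in 0.

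Tamoxifen, which blocks or activates estrogen receptors depending on the tissue, was compared with vehicle at 3.23 mg/kg. Gstp1 stood at 47.5 ± 1.49 CPM against 63.7 ± 2.34 (SD, n = 5), a log2 fold change of -0.42 ± 0.085 (SE). The splicing factor Smndc1 differed by 0.50 ± 0.1, the antiproliferative Tob2 by -0.57 ± 0.12, the cytochrome oxidase subunit Cox7c by 0.36 ± 0.082 and the glial septin Septin4 by -0.41 ± 0.086. Each had an adjusted p of 0.0935, as did Per3 at -0.34 ± 0.077. Of 18 immediate-early genes, which neuronal activity induces, 8 fell and 1 rose over the list alone, with Fos at -1.24 ± 0.39 and Dusp1 at -0.93 ± 0.24. None of the 18 passed over all genes, and the list's adjusted p with an estimated correlation was 0.558 (0.00257 at the preset one). Of the myelin genes, 3 of 15 fell over the list alone, Cnp, Mbp and Mag (adjusted p with an estimated correlation 0.558).

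For tamoxifen edgeR called 0 genes, with 2365 at an unadjusted p under 0.05, and DESeq2 called 83; with class in the model edgeR again called 0, with 1210. Leaving out tamoxifen replicate 2, replicate 1 or vehicle replicate 4 gave 666, 115 or 7 calls. Those tamoxifen libraries are the class A libraries of their group and vehicle replicate 4 is the class B vehicle library. Each omission therefore makes the compared groups differ more in class, which cannot be told apart here from a drug effect.

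Raloxifene, the other receptor modulator, was given at 9.68 mg/kg and had the largest count against vehicle, 3568 genes, in a comparison in which 5 class B libraries stand against 4 of class A and 1 of class B. As designed, 1929 genes rose and 1639 fell. Frat2, an inhibitor of the kinase Gsk3, fell by 1.52 on the log2 scale (SE 0.29), from 3.96 ± 0.41 to 1.37 ± 0.247 CPM (SD, n = 5). Epop, an elongin-binding partner of polycomb complexes, fell by 1.17, and Rps6ka6, a ribosomal S6 kinase, rose by 0.97 ± 0.22. Of 13 mitochondrially encoded genes, 11 rose, with Mt-nd4 at 7040 ± 197 against 4740 ± 502 CPM. Of 23 cholesterol synthesis and uptake genes, 7 rose and 1 fell, with Hmgcs1, the enzyme before the rate-limiting reductase, at 0.35 ± 0.08 and Idi1 at 0.69 ± 0.19. Of 16 circadian genes, 7 fell and 1 rose, with Dbp at -0.64 ± 0.11 and Per3 at -0.44 ± 0.077 (adjusted p 0.00613 for both). Of 70 cytosolic ribosomal protein genes, 20 fell and 2 rose, and of 15 myelin genes 4 fell, with Mbp, the myelin basic protein, going from 3620 ± 170 to 2610 ± 200 CPM. Among 16 GABAergic genes 5 rose and 2 fell, and the growth factors Ptn and Bdnf rose by 0.57 ± 0.12 and 0.51 ± 0.12. Of 17 pyruvate dehydrogenase and TCA cycle genes, 7 rose and 2 fell, and of 72 nuclear-encoded respiratory chain genes, 16 rose and 19 fell.

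Only Per3 among the 3568 genes passed with class in the model; it fell by 0.48 ± 0.087 on the log2 scale (adjusted p 0.0437) and passed in 2 of the 10 fits that leave out 1 library. The folds of the other genes named for raloxifene shrank. Frat2 went from -1.52 to -0.90 ± 0.26, Epop from -1.17 to -0.60 ± 0.26, Rps6ka6 from 0.97 to 0.60 ± 0.22, Idi1 from 0.69 to 0.17 ± 0.14 and Bdnf from 0.51 to 0.30 ± 0.12, while Dbp stayed nearer its value, from -0.64 to -0.54 ± 0.13. Mt-nd4 went from 0.57 to 0.15 ± 0.097 and Hmgcs1 from 0.35 to 0.14 ± 0.064. Ptn went from 0.57 to 0.17 ± 0.063 and Mbp from -0.47 to -0.31 ± 0.11. Without single libraries the fold with class ran from 0.00819 to 0.219 for Mt-nd4 and 0.0755 to 0.166 for Hmgcs1. It ran from 0.0955 to 0.195 for Ptn, 0.0672 to 0.223 for Idi1 and -0.998 to -0.51 for Frat2. The median of the mitochondrially encoded genes went from 0.394 to 0.0953, and that of the respiratory chain genes changed sign, from -0.0814 to 0.0532. Every list named for raloxifene had an adjusted p of 0.948 with an estimated correlation; at the preset correlation the mitochondrially encoded (1.16e-05) and ribosomal (0.00708) lists passed.

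For raloxifene the authors' per-gene factors gave 924 calls, 68.8% of them higher, against 54.1% as designed, and the class B libraries alone, with 1 vehicle library, gave 24. As designed the count was 2339 and 1793 without raloxifene replicates 1 and 5, 1824, 2110 and 1801 without vehicle replicates 1, 2 and 3, and up to 4590 without any other library.

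**Figure D3:**
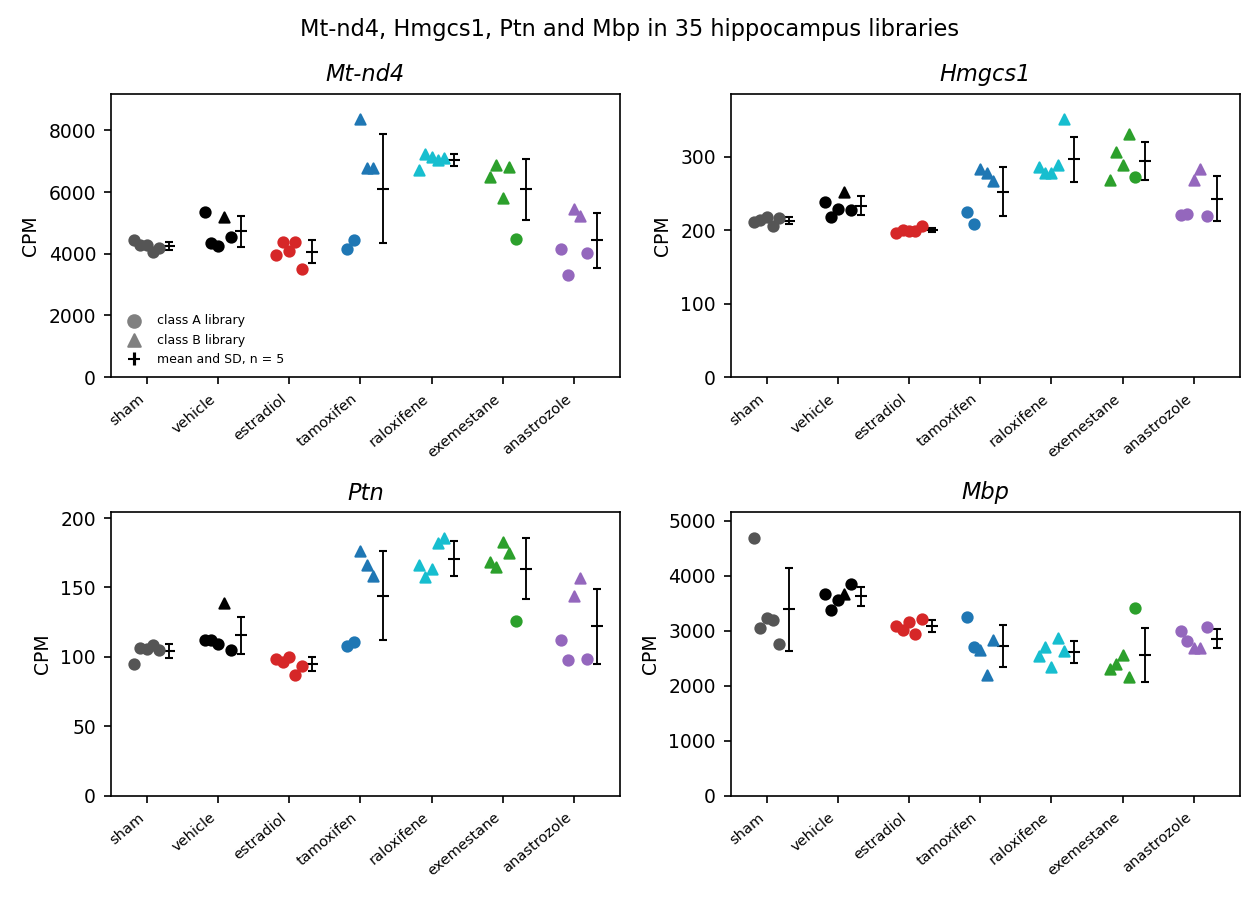
Expression (CPM, y axis) of Mt-nd4, Hmgcs1, Ptn and Mbp in each library of the 7 groups, with circles for class A, triangles for class B and the mean ± SD of 5 libraries beside them. Ptn stood at 171 ± 12.3 CPM in raloxifene, 164 ± 22 in exemestane and 115 ± 13.5 in vehicle, where the class B library, at 139, lay above the 4 class A libraries.

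Exemestane, a steroidal aromatase inhibitor given at 0.16 mg/kg per the labels, asks with anastrozole what remains once estradiol synthesis outside the ovaries is blocked. As designed 938 genes passed against vehicle, 585 of which rose and 353 of which fell, with 4 class B libraries against 1. Galr1, a galanin receptor, rose by 1.28 ± 0.35 (SE; 4 ± 0.881 against 1.65 ± 0.793 CPM, SD, n = 5), the acute-phase gene Serpina3n by 1.11 ± 0.34 and the matrix proteoglycan Dcn by 0.83 ± 0.19. Enpp6, a marker of newly forming oligodendrocytes, fell by 1.28 on the log2 scale and Mfsd14a, a transporter-like protein, by 1.87. Of 15 myelin genes 4 fell, Mbp by 0.50 and Cnp by 0.41, though the myelin score lay below these vehicle libraries in every group, sham included. Of 18 immediate-early genes 3 fell over all genes and 8 over the list alone, with Junb at -0.86 ± 0.25. Of 14 endothelial genes 2 fell, among them the tight-junction claudin Cldn5 at -0.52 ± 0.13, and of 17 microglial genes 2 fell, among them the receptor Csf1r at -0.32 ± 0.083. Of 70 ribosomal protein genes 9 fell and 0 rose, and Hmgcs1 and Idi1 were among 3 of 23 cholesterol genes that rose. Dbp fell by 0.49 on the log2 scale.

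For exemestane edgeR with class in the model called 0 genes, with 1004 at an unadjusted p under 0.05; DESeq2 called 1979 and edgeR on the exemestane and vehicle libraries alone called 0. In the fit with class Galr1 stood at 1.36 ± 0.38, Enpp6 at -1.27 ± 0.36, Dcn at 0.64 ± 0.2, Mbp at -0.39 ± 0.11, Cnp at -0.35 ± 0.1 and Dbp at -0.42 ± 0.12, near their folds as designed. Serpina3n shrank from 1.11 to 0.35 ± 0.26, Mfsd14a from -1.87 to -1.13 ± 0.34, Junb from -0.86 to -0.43 ± 0.23, Cldn5 from -0.52 to -0.23 ± 0.094, Csf1r from -0.32 to -0.20 ± 0.076, Idi1 from 0.73 to 0.31 ± 0.14 and Hmgcs1 from 0.33 to 0.18 ± 0.06. Without single libraries the fold with class ran from -0.519 to -0.293 for Mbp and -0.538 to -0.244 for Cnp. It ran from 0.123 to 0.421 for Serpina3n and -0.617 to -0.237 for Junb. The adjusted p with an estimated correlation was 0.801 for the myelin, immediate-early, endothelial, microglial and ribosomal lists and 0.993 for the cholesterol list. The count as designed was 4121 without exemestane replicate 5, the group's class A library, 2787 without vehicle replicate 4, the class B vehicle library, and 0 or 1 without any other library.

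Anastrozole, a non-steroidal aromatase inhibitor given at 4.03 mg/kg, was compared with vehicle in the same way. The value of smallest p was that of Plekhb1, a membrane protein first found in photoreceptors, at 145 ± 15.2 against 198 ± 10.4 CPM (SD, n = 5; log2 fold change -0.45 ± 0.11 SE). Per3 followed at -0.30 ± 0.077, and the growth factor homologue Fgf11 stood at 0.36 ± 0.098, each with an adjusted p of 1. Of 15 myelin genes 4 fell over the list alone, among them Mbp at -0.35 ± 0.11 and Opalin at -0.39 ± 0.14; the list's adjusted p with an estimated correlation was 0.283, against 1.37e-10 at the preset one. For anastrozole edgeR called 0 genes, with 414 at an unadjusted p under 0.05, and DESeq2 called 2; with class in the model edgeR called 0, with 1088. The 95% interval of a gene's log2 fold change reached a median of 0.257 on either side.

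Tamoxifen and raloxifene, both receptor modulators but of different structure, were compared directly, at doses that differ. Adgrf5, an adhesion receptor of blood vessels, stood at 55.1 ± 7.45 CPM under tamoxifen and 74.9 ± 4.72 under raloxifene (SD, n = 5; log2 fold change -0.45 ± 0.085 SE, 95% interval -0.62 to -0.27, adjusted p 0.116). Lpar6, a lysophosphatidic acid receptor, differed by -1.03 ± 0.21 (0.116), and Tek, the angiopoietin receptor of endothelium, by -0.53 ± 0.12 (0.219). Of 14 endothelial genes 2 were lower under tamoxifen over the list alone and 0 over all genes (adjusted p with an estimated correlation 0.936). No gene passed in edgeR, with 1212 at an unadjusted p under 0.05, and DESeq2 called 6. With class in the model edgeR called 0, with 587, and the 95% interval of a gene reached a median of 0.26 as designed and 0.221 with class on either side, so smaller differences between the compounds remain undetermined.

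Exemestane, a steroid, and anastrozole, a triazole, were also compared directly, again at doses that differ and that could not be checked beyond the labels. Zkscan7, a zinc finger protein, stood at 8.5 ± 1.02 CPM under exemestane and 5.03 ± 1.1 under anastrozole (SD, n = 5; log2 fold change 0.75 ± 0.15 SE, adjusted p 0.0519). Dcx, a microtubule protein of young neurons, differed by 0.56 ± 0.13 and Rims3, a protein of the presynaptic active zone, by -0.74 ± 0.16 (0.0901 for both). Of the genes tested, 4 passed with class in the model. Chm, a Rab escort protein, was higher under exemestane by 0.45 ± 0.073 (adjusted p 0.00772), Ccdc88a, which binds actin, by 0.31 ± 0.059 (0.0264) and an entry without a symbol by 0.34 ± 0.064 (UNKNOWN_ENSRNOG00000062127, 0.0241); Chpf, an enzyme of chondroitin synthesis, was lower by a log2 fold change of -0.28 ± 0.052 (0.0241). As designed these 4 stood at 0.69 ± 0.17, 0.56 ± 0.16, 0.54 ± 0.14 and -0.49 ± 0.12, each with an adjusted p of 0.0901. Over the list alone 10 of 13 mitochondrially encoded genes were higher and 9 of 21 glycolysis genes lower under exemestane as designed, and 0 over all genes. With class these list counts were 4 and 2, and the adjusted p with an estimated correlation as designed was 0.856 for both lists. Without 1 library, Chm passed in 9 of 10 fits with class, Chpf and UNKNOWN_ENSRNOG00000062127 in 4 and Ccdc88a in 3. That count was 0 without anastrozole replicate 3, 1 without anastrozole replicate 1 or 2 or exemestane replicate 3, 2 without anastrozole replicate 4 or exemestane replicate 4, 7 without exemestane replicate 5 and 22 without exemestane replicate 1.

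For exemestane against anastrozole edgeR called 0 genes as designed, with 3900 at an unadjusted p under 0.05, and DESeq2 called 854. Leaving out exemestane replicate 5, anastrozole replicate 4 or anastrozole replicate 3 gave 3391, 2707 or 1587 calls. Exemestane replicate 5 is the class A library of its group, and these anastrozole libraries are the class B libraries of theirs. Each omission therefore makes the compared groups differ more in class. In class B alone the count was 13.

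**Figure D4:**
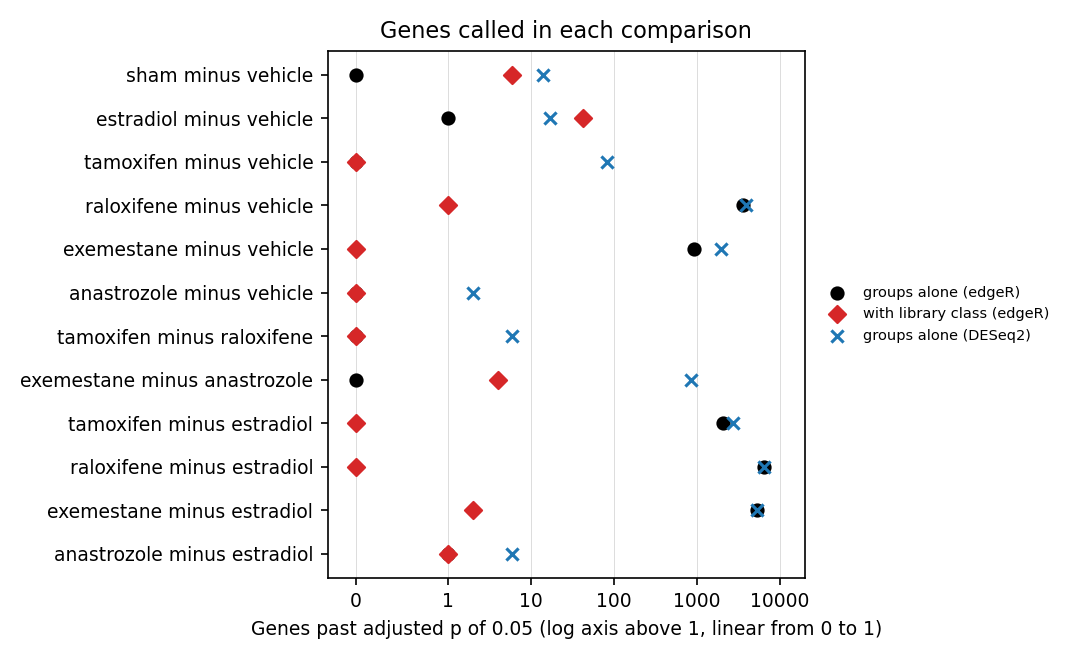
Number of genes past an adjusted p of 0.05 (x axis, log above 1) in the 12 comparisons (y axis), by edgeR on the groups alone (circles), edgeR with class (diamonds) and DESeq2 on the groups alone (crosses). Raloxifene against vehicle went from 3568 to 1 when class was added, and estradiol against vehicle from 1 to 43.

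Each drug was also set against estradiol, which tests directly whether its effect differs from that of the hormone. Vgf was lower than under estradiol, with a log2 fold change of -0.94 ± 0.14 for raloxifene (SE; 67 ± 6.39 against 129 ± 10.8 CPM, SD, n = 5), -0.90 ± 0.14 for exemestane and -0.65 ± 0.14 for tamoxifen. In the fit with class these Vgf folds were -0.40 ± 0.099 (adjusted p 0.295), -0.46 ± 0.093 (0.0856) and -0.36 ± 0.085 (0.352), none past the threshold. Hmgcs1 was higher by 0.57 ± 0.081 under raloxifene and 0.55 ± 0.081 under exemestane, and Eng was lower under tamoxifen, with a log2 fold change of -0.71 ± 0.12; with class the raloxifene fold of Hmgcs1 was 0.31 ± 0.069 (adjusted p 0.194) and that of Eng -0.54 ± 0.11 (0.16). All 13 mitochondrially encoded genes were higher under raloxifene than under estradiol (adjusted p of the list 0.965 with an estimated correlation). As designed 2053 genes differed for tamoxifen, 6431 for raloxifene and 5304 for exemestane. In these comparisons all 5 estradiol libraries are class A, and with class in the model the counts were 0, 0 and 2, with 1085, 1042 and 1356 genes at an unadjusted p under 0.05. The 2 exemestane genes were Ptn, at 0.37 ± 0.063 (adjusted p 0.0172; 0.78 ± 0.13 as designed), and Hmgcs1, at 0.35 ± 0.064 (0.0278; 293 ± 25.8 against 200 ± 3.14 CPM); they passed in 7 and 4 of the 10 fits that leave out 1 library. For anastrozole 1 gene passed in both fits, Mt-ENSRNOG00000030478, at 589 ± 72.8 against 1070 ± 61.1 CPM (log2 fold change -0.86 ± 0.12, adjusted p 0.000514; -0.76 ± 0.11 and 0.00345 with class). The tamoxifen count was 0 without tamoxifen replicate 3, 4 or 5, each of class B, 1 and 2 without estradiol replicates 1 and 5, and 4236 without tamoxifen replicate 2.

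Across all 7 groups 5329 genes differed as designed and 4 with class in the model. The 4 were Mt-ENSRNOG00000030478, Vgf, Per3 and Rims3, with adjusted p of 0.0119, 0.0214, 0.0491 and 0.0491. Leaving out single libraries moved that count from 1, without estradiol replicate 1, to 35, without sham replicate 1; it was 19 without exemestane replicate 5, 13 without estradiol replicate 2 and 2 to 12 without any other library. Rims3 was at a mean of 22.5 CPM in sham, 16 in vehicle, 14.8 in estradiol, 10.8 in tamoxifen, 11.1 in raloxifene, 9.39 in exemestane and 15.8 in anastrozole. Per3 was at 61.1 CPM in vehicle and at 44.9 to 52.9 in the other groups.

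The responses were last compared gene by gene with that to estradiol, as log2 fold changes against the same vehicle libraries. Across 14411 genes, which are not independent replicates, Pearson's r with estradiol was 0.445 for sham, 0.16 for tamoxifen, -0.0466 for raloxifene, -0.0152 for exemestane and 0.346 for anastrozole. Simulated groups without any effect gave a median r of 0.514, from 0.136 to 0.76, because both folds share the vehicle libraries. With class in the model the values were 0.37, 0.478, 0.43, 0.414 and 0.436 against a simulated median of 0.506. With the vehicle libraries also split between the 2 folds, they were 0.00228, 0.0643, 0.0462, 0.0154 and 0.0255, so no similarity beyond the shared controls was measurable.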

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

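The tests of library class on the genes called for raloxifene and for exemestane were set before their result was seen; the tests of choroid plexus tissue and of each drug as the whole cause, and every fit with class, were chosen afterwards.

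In the drug groups set against estradiol, 2053 genes differed for tamoxifen, 6431 for raloxifene, 5304 for exemestane and 1 for anastrozole, each by a direct test of the drug against the hormone. With class in the model these counts were 0, 0, 2 and 1. The genes called against vehicle, 3568 for raloxifene and 938 for exemestane, were held against library class in other groups. Of the raloxifene genes, 99% had the same sign as the class B minus class A difference within tamoxifen, exemestane and anastrozole, and of the exemestane genes 98.1% had the same sign as that within tamoxifen and anastrozole; over all genes these shares were 84.4% and 81.8%. With class in the model 1 and 0 of them stayed called, which argues against either drug as the whole cause. For raloxifene the median absolute log2 fold change went from 0.377 to 0.087 and the median SE from 0.113 to 0.0887; for exemestane they went from 0.403 to 0.176 and from 0.113 to 0.0819, so the median fold shrank and the spread did not grow. Some calls ended at about the same fold and spread, such as Galr1 under exemestane (1.28 ± 0.35 to 1.36 ± 0.38, adjusted p 0.0426 to 0.465) and Enpp6 (-1.28 ± 0.33 to -1.27 ± 0.36, 0.0394 to 0.468), where the adjustment over all genes became stricter, since 1004 genes against 4519 as designed had an unadjusted p under 0.05. Choroid plexus tissue is argued against, since the raloxifene count was 4034 with its score in the model. Library class, whose origin the labels do not give, is therefore a likely cause of part of both counts. How large a part stays open. A simulated class effect without a treatment effect gave 1621 calls for raloxifene and 0 for exemestane, in 1 draw with genes that varied independently. With class in the model 100% of the exemestane genes and 90.6% of the raloxifene genes kept their direction. Both fits use the libraries from which these genes were picked, so this does not measure a share of the drugs.

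Other splits of the same libraries were counted for each comparison. Of 21 splits, the real one gave the most calls for raloxifene against vehicle (3568 genes, highest other split 45) and exemestane against vehicle (938, 22). So it did for raloxifene and exemestane against estradiol (6431 and 5304, highest other 0 in both). It did so too among the 7 groups (5329, 2106) and, with class in the model, for estradiol against vehicle (43, 1). For anastrozole against estradiol (1, highest other 0 of 21 splits) the count is a single gene. With 21 splits the smallest possible share is 1 in 21, and no adjustment was made over the comparisons. Such counts make chance less likely and do not exclude it. Another split gave as many calls for sham against vehicle with class (6, highest other 6, reached in 2 of 21 splits). The same was true of estradiol against vehicle as designed (1, highest other 1, 2 of 21 splits). Where edgeR called 0 genes as designed (sham, tamoxifen and anastrozole against vehicle and both comparisons within a drug class), all 6 splits give as many by construction, so they say nothing about chance. For tamoxifen against estradiol (2053, highest other 3252) another split gave more calls. The split with 3252 keeps the 3 class B libraries on one side, and the value with class is 0. A count above the other splits does not set the drug apart from library class. Splits with the class balance of the real one gave fewer calls. For raloxifene (5 class B libraries against 1) the split drawn gave 45. For exemestane (4 against 1) such splits gave 0, 22 and 0. These splits match only the sign of class and are few, so they cannot decide whether class balance is the whole cause. The raloxifene split put vehicle replicate 4 on the drug side. On the first component of the authors' per-gene factors that library lay at -0.1048 and the raloxifene libraries at -0.2375 to -0.1555. The exemestane count also fell to 0 or 1 without any library but exemestane replicate 5 or vehicle replicate 4, so any regrouping could lower it.

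Single libraries far from the other 4 of their group were found in 26 of 211 groups of values; chance gives about 1 in 20. Exemestane replicate 5, the class A library of its group, stood apart in Rn7sl1 at 5.81% of counts (Wilson 95% interval 5.79 to 5.822, counting error only; others 3.51 to 3.84) and in CPM of Mfsd14a (10.8; others 0.587 to 3.5), Cnp (389; 248 to 278), Cldn5 (31.8; 24.7 to 26.3), Idi1 (19.8; 32.7 to 36.3), Dcx (39.9; 63.2 to 66.6), Rims3 (12.2; 8.36 to 9.24), Chm (33.2; 49.1 to 55.2), Ccdc88a (115; 172 to 194) and Chpf (98; 66.9 to 74). Vehicle replicate 4, the class B library of its group, stood apart in Rn7sl1 (3.44%, interval 3.426 to 3.453; others 4.68 to 4.84), Ptn (139 CPM; 105 to 112) and the mean of the myelin list (7.82 log2 CPM; 7.28 to 7.42).

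Sham replicate 1 had Tcf7l2 at 90.8 CPM (others 9.21 to 14.4) and a mean of 4.22 log2 CPM for the thalamus and habenula list (2.72 to 3.12). Estradiol replicate 2 had a mean of 5.46 log2 CPM for the choroid plexus list (-0.669 to -0.335) and Nr1d2 at 76.7 CPM (67.4 to 68.5), and estradiol replicate 5 had Mt-ENSRNOG00000030478 at 960 CPM (1070 to 1110) and Xbp1 at 37.7 CPM (40.3 to 40.9). Vehicle replicate 2 had Per3 at 53.1 CPM (62.3 to 64), Frat2 at 4.68 CPM (3.69 to 3.9) and Tcf7l2 at 9.46 CPM (11.6 to 12.3), and vehicle replicate 1 had Arntl at 31.9 CPM (26.5 to 27.9) and Galr1 at 3.03 CPM (1.14 to 1.63). Raloxifene replicate 5 had Hmgcs1 at 351 CPM (277 to 289), and anastrozole replicate 1 had Rims3 at 20.3 CPM (14.3 to 15).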

How the results depend on the processing

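Alternatives with library class, with the authors' per-gene factors and within 1 class were chosen after seeing the data. Counts of called genes that were more than 1.5 times away from the value as designed are given by setting. The cause was not tested except for class, and single-class fits also hold fewer libraries.

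With class, sham gave 6, estradiol 43, raloxifene 1 and exemestane 0 genes against vehicle, exemestane against anastrozole 4, tamoxifen, raloxifene and exemestane against estradiol 0, 0 and 2, and the 7 groups 4. With class and the choroid plexus score the same counts were 7, 35, 1, 0, 7, 0, 0, 2 and 17. With surrogate variables they were 12, 14, 1, 5, 1, 0, 0, 0 and 15. With the choroid plexus score alone sham gave 5, estradiol 0 and exemestane 1462. DESeq2 called 14 for sham, 17 for estradiol, 83 for tamoxifen, 1979 for exemestane, 2 for anastrozole, 6 for tamoxifen against raloxifene, 854 for exemestane against anastrozole and 6 for anastrozole against estradiol.

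With the authors' per-gene factors, estradiol gave 4, tamoxifen 21, raloxifene 924 and exemestane 134 against vehicle; the 4 drugs, in the order tamoxifen, raloxifene, exemestane, anastrozole, gave 232, 3137, 2320 and 0 against estradiol, and the 7 groups 2551. With only the 2 groups in the fit, estradiol gave 27, exemestane 0, exemestane against anastrozole 1 and tamoxifen against estradiol 0. In class A alone, estradiol gave 9 and exemestane 0 against vehicle, and tamoxifen, exemestane and anastrozole gave 0, 2 and 0 against estradiol. In class B alone, where vehicle has 1 library that is assumed to vary like the other groups, tamoxifen gave 148, raloxifene 24, exemestane 104, anastrozole 5 and exemestane against anastrozole 13. RLE factors moved 1 count, that of exemestane against anastrozole, to 3, and no filter moved none.

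Leaving out single libraries gave, as designed, 0 to 2 genes for sham, 0 to 2 for estradiol, 0 to 666 for tamoxifen (666 without tamoxifen replicate 2), 1793 to 4590 for raloxifene (1793 without raloxifene replicate 5), 0 to 4121 for exemestane (4121 without exemestane replicate 5), 0 to 0 for anastrozole, 0 to 1 for tamoxifen against raloxifene, and 0 to 3391 for exemestane against anastrozole (3391 without exemestane replicate 5). Against estradiol it gave 0 to 4236, 5427 to 6282, 4026 to 6491 and 1 to 1 for tamoxifen, raloxifene, exemestane and anastrozole, and 4665 to 6140 for the 7 groups. With class it gave 0 to 7 for sham, 2 to 64 for estradiol (2 without vehicle replicate 5), 0 to 2 for tamoxifen, 0 to 1 for raloxifene, 0 to 9 for exemestane, 0 to 4 for anastrozole, 0 to 1 for tamoxifen against raloxifene, 0 to 22 for exemestane against anastrozole, 0 to 3, 0 to 0, 0 to 6 and 1 to 1 for the 4 drugs against estradiol and 1 to 35 for the 7 groups.

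Of the list tests 0 passed as designed, 72 at the preset correlation and 78 with class and the preset correlation. With the choroid plexus score 2 passed, and 0 to 2 without single libraries. Those with the score were 1 list higher in sham (camera adjusted p 0.0141) and 1 higher in estradiol (0.00602), each against vehicle. Cell type and RNA quality scores gave 0 to 0. The correlation with estradiol moved for sham to 0.0314 with split controls and 0.00228 with class as well, for tamoxifen to -0.0408 at 10 CPM or more, 0.478 with class and -0.193 with split controls, for raloxifene to -0.289, 0.43 and -0.311 and for exemestane to -0.229, 0.414 and -0.298 in the same order. For anastrozole it moved to -0.0883 with split controls and 0.0255 with class as well. Without single libraries it ran from 0.329 to 0.541 for sham, 0.0321 to 0.283 for tamoxifen, -0.0945 to 0.053 for raloxifene, -0.113 to 0.0877 for exemestane and 0.188 to 0.496 for anastrozole, so the sign for raloxifene and exemestane rests on single libraries, vehicle replicate 5 among them.

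Among the values of named genes under the alternatives, 737 kept their direction and side of the threshold, 132 passed it where the designed value did not, 171 no longer passed and 2 changed direction. The 2 were Cnp under exemestane, at 0.0545 in class A alone, and Junb under exemestane, at 0.0461 in class B alone. Depth limits the low genes: Esr2, with a median of 1.08 CPM, cannot be followed as Pgr can, at 22.8 CPM.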

Other observations

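The test of the time of collection and the test of a single vehicle library were set before their result was seen; the tests of ovarian hormone and all tests of the estradiol calls were chosen afterwards, as were the gene groups described first.

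Prox1, the transcription factor of dentate granule cells, and Dsp, a desmosomal protein of the same cells, differed by -0.33 and -0.60 in log2 fold change between sham and vehicle and were among 4 dentate granule genes that fell over the list alone, while 1 rose (Pdzd2, 0.18); the adjusted p with an estimated correlation was 0.358. Of 72 nuclear-encoded respiratory chain genes, 59 were higher under estradiol than under vehicle (median 0.0835, adjusted p with an estimated correlation 0.356), while the 13 mitochondrially encoded genes had a median of -0.254 (0.534). Under anastrozole with class in the model, 10 of these 13 fell over the list alone (median -0.23, 0.248).

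Mepce, which caps 7SK RNA, was at 0 counts in all 5 raloxifene libraries. Against vehicle (4.65 ± 1.94 CPM, SD, n = 5) it was at least 11.2-fold lower, taking a floor of 3 counts per library. It was also at 0 in 21 of the 35 libraries, so a quantification that drops the gene in some libraries is not ruled out.

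Dbp and Per3 lay below vehicle in all 6 other groups with class in the model, Dbp by log2 folds of -0.569 in sham, -0.532 in estradiol, -0.336 in tamoxifen, -0.539 in raloxifene, -0.42 in exemestane and -0.284 in anastrozole. The mean of both genes in the aromatase inhibitor groups, which lack ovarian hormone, was -0.311, against -0.452 in sham and estradiol. This argues against ovarian hormone alone, unless the vehicle mean is high by chance, since all folds share the vehicle libraries. Both genes were picked from these same data. For the 6 groups together against vehicle, the edgeR adjusted p with class was 0.00728 for Per3 and 0.0516 for Dbp. A single vehicle library is argued against as well, since the sham fold of Dbp stayed at -0.534 or further from 0 without each in turn. An earlier or later time of collection for the vehicle animals may explain the pattern and cannot be told apart from a treatment effect: 14 of 18 folds of 3 genes of opposite phase were positive, too few to decide, and the labels give no hour. Arntl was positive in every group, while Npas2 and Clock went both ways. Of the other clock genes, Nr1d1, Nr1d2, Tef and Ciart lay below vehicle in every group and Cry1 above it. Per1, Per2, Cry2, Hlf, Bhlhe40 and Bhlhe41 went both ways.

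The 43 genes called for estradiol once class was in the model, against 1 as designed, were examined in the same way. Many of them were entries with an Ensembl identifier only, all higher under estradiol. Whether the class B vehicle library also hid them stays open. In edgeR as designed 0 genes passed without vehicle replicate 4 (759 at an unadjusted p under 0.05). That fit still held the groups of mixed class, so it could call few genes either way. With class in the model the count without that library was 64. DESeq2, on all libraries, called 17 as designed. Choroid plexus tissue is argued against, since 30 of the 43 stayed called with its score added. Class differences inside the other groups, which widen the spread that edgeR shares between groups, are a likely cause. Of the 43, 12 were called in a fit of the estradiol and vehicle libraries alone. Over all genes the 95% interval reached a median of 0.262 on either side as designed and 0.216 with class. Over the 43 the median SE went from 0.118 to 0.0836 while the median absolute fold went from 0.454 to 0.432. Those genes were picked for passing with class, so their SE adds no support. The higher Vgf, Fkbp4 and Stip1 under estradiol may be an effect of the hormone, a hypothesis found and tested on the same libraries. Class is only the sign of a graded component, though. On it the estradiol libraries lay at 0.142 to 0.211 and the 4 class A vehicle libraries at 0.0668 to 0.138. Their Rn7sl1 shares were 4.99 to 5.88% and 4.68 to 4.84%. Such a remaining difference was not tested and cannot be told apart from the hormone. Vgf also lay lower in the class B libraries of tamoxifen and anastrozole. Without vehicle replicate 5 the count was 2. Of 10 fits that leave out 1 library, Vgf passed in 10, Fkbp4 in 8 and Stip1 in 6.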
